A study of Mus musculus with 9 samples.

How the data were processed

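The labels name total RNA as the molecule and the design text speaks of mRNA, and how mRNA was selected is not given in the sources used here. Per the labels' protocols RNA was extracted with Trizol, its integrity was checked on a Bioanalyzer, and libraries were made by standard Illumina methods. Per the submitters' processing notes the reads were aligned with HISAT2 to the mouse genome build mm10. The version of the aligner, the counting tool, the annotation and the strand setting are not given in the sources used here, so overlapping and antisense genes cannot be told apart. The deposited table holds raw counts per gene symbol as the authors made them, with 46095 symbols and 9 columns, each matched to its library by the title in the labels, and no replicates were pooled. Values are whole numbers with a different total in each library, from 29633411 to 32798920. Counting error is therefore small for all but genes with a few counts, and intervals and floors given for those cover counting error only.

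Genes with too few counts were removed with filterByExpr over the 3 groups (minimum count 10), which left 14026 genes with 99.956% of the counts and removed 32069. Counts were scaled with TMM factors and fitted with edgeR 4.0.16 in R 4.3.3 as a quasi-likelihood model with robust dispersion, with the group as the only term over all 9 libraries (6 residual degrees of freedom, biological coefficient of variation 6.72%). Tests were two-sided with Benjamini-Hochberg adjustment at 0.05. CPM are counts scaled by the TMM-adjusted library total, and errors are SD over 3 libraries for CPM and SE for log2 fold changes. That SE is the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. It is therefore derived from the test and only approximate, above all for genes with few counts in a group. A fold against a group with 0 counts was computed against a floor of 3 counts over the group, or in control replicate 1 where that was the only control library kept. For 1 to 3 counts the ratio is given with its exact 95% interval.

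A set of 31 gene lists was fixed before the data were examined, of which 28 had at least 5 tested members. They were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 and adjusted over the 28 lists of each comparison. Median, mean and test differed in sign for the interferon, ketone body, inflammasome, oxidative stress and stromal lists in LPS against control, for the inflammatory, interferon, oxidative stress, stromal and mitochondrially encoded lists in LPS plus BHB against LPS, and for the interferon, ketone body, oxidative stress, class II, stromal and immediate early lists in LPS plus BHB against control. The same test with an estimated correlation called none of them in any comparison. The lists of lymphocyte, of erythroid and megakaryocyte, and of mast cell and basophil markers had 3, 4 and 2 tested members and were not tested as lists. In LPS plus BHB against LPS, 0, 2 and 2 of their genes were higher and 1, 1 and 0 lower. In LPS against control 1, 0 and 1 were higher and 2, 3 and 0 lower. In LPS plus BHB against control 1, 0 and 2 were higher and 2, 2 and 0 lower. The genes named are, for each comparison, the 5 largest rises and falls among called genes with a mean of at least 5 CPM and groups that do not overlap, the 3 members with the smallest p in each list, and genes fixed in advance. Some genes that the rule selects are not reported here. Any other gene named was chosen after its values were seen. Coordinates are those of the GRCm38 annotation, the build that mm10 names, and the table itself gives symbols only.

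Replicates differed by more than sampling noise, with chi-square per degree of freedom from 3.10 to 10.4, and all 9 were counted separately. Relations between comparisons that share libraries were set beside 20 simulations of unchanged groups. The gene test was tested on simulated data with 200 changed genes. For LPS against control it recovered 77.6%, 92.5% and 95.5% of those changed 1.5-fold, 2-fold and 4-fold, with 12 false calls among 13125 unchanged genes. For LPS plus BHB against LPS it recovered 73.1%, 88.1% and 98.5%, with 7 among 12772, and for LPS plus BHB against control 76.1%, 83.6% and 98.5%, with 12 among 13131. Only 200 genes were changed in each simulation, whereas 11191, 7115 and 10990 of 14026 genes were called in the data. These rates therefore do not cover data in which so many genes change. The list test called 0 of 20 unchanged lists in each comparison. Those lists were random sets of genes simulated independently of each other. The estimated correlation of the fixed lists reached 0.478 (type I interferon), so this check does not cover false calls for correlated genes.

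Alternatives chosen before the data were examined were DESeq2's size factors within edgeR, no filter on low counts, DESeq2 1.42.0, a replicate block, fits of the 6 libraries compared, glmTreat against a fold of 1.5, camera with an estimated correlation, fry, and leaving out each library. Scaling by library totals alone, a non-robust prior, and leaving out control replicates 2 and 3 were chosen after seeing the data. Shared sequence was measured as the share of a gene's 31-base words found in annotated transcripts of other genes. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.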

Results

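Messenger RNA was profiled by sequencing in bone marrow-derived macrophages, which are macrophages grown in culture from marrow precursor cells, from wild-type Balb/c mice whose age the labels give as 6 weeks. The 9 libraries formed 3 groups of 3: control, LPS, and LPS plus BHB. The labels spell out neither abbreviation and give no dose or time. LPS commonly stands for lipopolysaccharide, a bacterial cell wall component that activates macrophages through Toll-like receptor 4, and BHB for the ketone body beta-hydroxybutyrate. No library received BHB without LPS. Total counts were 30809141, 32798920 and 31445850 in the control libraries, 32100107, 30123021 and 29633411 in the LPS libraries, and 32228186, 31543471 and 30767004 in the LPS plus BHB libraries. Of 46095 gene symbols listed, 24589 had at least 1 count and 14026 were tested. The labels do not say that the replicates came from separate cultures or animals, so the p-values measure only the spread between these samples. The first principal component of log2 CPM held 80.4% of the variance and parted the control libraries from both treated groups, and the second held 11.3% and parted LPS plus BHB from LPS.

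**Figure D1:**
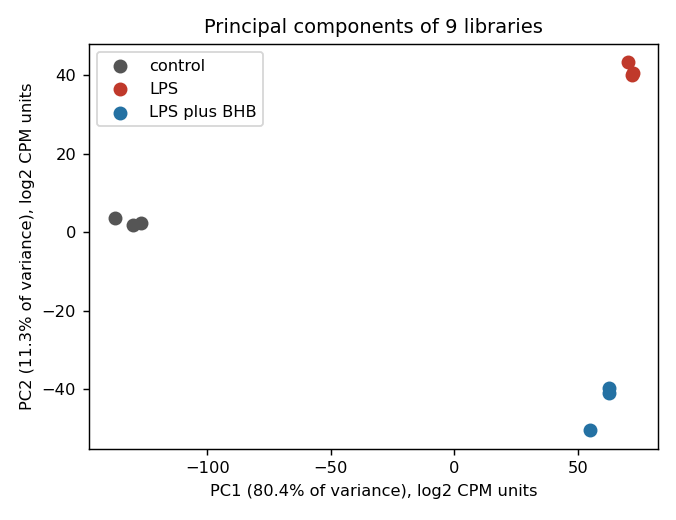
Scores of the 9 libraries on the first (x axis, 80.4% of variance) and second (y axis, 11.3%) principal components of log2 CPM, one point per library, coloured by group. The 3 libraries of each group lie together and apart from the other groups. LPS plus BHB replicate 3, at -50.5 on the second component, lies somewhat away from replicates 1 and 2, at -41.1 and -39.8.

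The comparison of LPS with control asked how the macrophage transcriptome responded to LPS. The 5 largest rises by the fixed rule included genes for a cytokine, a growth factor and an enzyme of macrophage activation. Il12a, which encodes a subunit of interleukin 12, went from 0.174 ± 0.235 CPM in control to 82.8 ± 4.49 CPM with LPS (SD, n = 3; log2 fold change 8.86, SE 0.27), Nos2, the inducible nitric oxide synthase, from 1.10 ± 0.966 to 493 ± 15.4 CPM (8.78, SE 0.43), and Csf2, which encodes the growth factor GM-CSF, from 0.262 ± 0.230 to 109 ± 2.68 CPM (8.67, SE 0.48). With all control libraries the largest of these was that of the collagen gene Col27a1 (chromosome 4, 63214009 to 63334991, GRCm38), from 0.209 to 156 CPM (log2 fold change 9.51, SE 0.16). Vnn3 had 3 counts over the control libraries, a ratio of 526 with a counting interval of 180 to 2554. These folds depend on low counts in control replicates 2 and 3, and against control replicate 1 alone, which had 0 counts of Nos2, Csf2 and Il12a, they were at least 5854, 1300 and 982 (floor of 3 counts in that library), and the ratio for Col27a1 was 2780 with a counting interval of 769 to 22959. The order of these rises is therefore not settled. Among the falls, St6gal1, a sialyltransferase (chromosome 16, 23224729 to 23360350), dropped from 169 ± 3.30 to 0.781 ± 0.0815 CPM (log2 fold change -7.75, SE 0.12), and Amica1 had a log2 fold change of -8.51 (SE 0.28). Npas4 had no count in the LPS libraries and was at least 580-fold lower, against a floor of 3 counts over the group. All of these had adjusted p-values between 5.33e-21 and 2.37e-06 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The fixed rule required that the 3 libraries of one group lie above the 3 of the other, so that separation is no added support.

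All 23 tested inflammatory cytokines and chemokines rose with LPS (23 adjusted over the list alone), with a median log2 fold change of 6.73. Among the genes fixed in advance, Il6 rose by a log2 fold change of 7.90 (SE 0.35), Il1b by 5.99 (SE 0.31) and Il12b by 8.19 (SE 0.65). Against control replicate 1 alone Il6 was at 11.38 and Il1b at 6.77, Il12b was at least 13827-fold higher, and 21 of 23 genes passed, with a median of 7.95 with 4 genes at their lower bound. The list stood above other genes by camera (adjusted p = 8.02e-06, and adjusted p = 0.400 with an estimated correlation). Of 19 classical activation effectors 18 rose and 1 fell, including Acod1, which makes itaconate, at 7.45 (SE 1.16), or 13.03 against control replicate 1 alone (camera adjusted p = 2.23e-05, and adjusted p = 0.329 with an estimated correlation). Feedback inhibitors of Toll-like receptor and NF-kB signalling rose in 18 of 20 cases and fell in 2, with Nfkbia, which encodes the inhibitor I kappa B alpha, going from 60.5 to 1298 CPM (camera adjusted p = 2.85e-05, and adjusted p = 0.329 with an estimated correlation). All 20 genes of the integrated stress and unfolded protein response rose, among them Herpud1 at 4.43 (SE 0.05) and Ppp1r15a at 5.27 (SE 0.06; camera adjusted p = 2.29e-08, and adjusted p = 0.329 with an estimated correlation). Components of Toll-like receptor signalling rose in 15 and fell in 8 of 24 cases (camera adjusted p = 0.0265, and adjusted p = 0.329 with an estimated correlation). Nfkb2 rose by 4.17 (SE 0.05), while Tlr4, the LPS receptor gene, fell from 169 to 27.2 CPM.

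Macrophage identity genes fell in 16 and rose in 3 of 19 cases, with the Fc receptor gene Fcgr1 at -6.49 (SE 0.10; camera adjusted p = 0.000777 for the list, and adjusted p = 0.400 with an estimated correlation). Lysosome and phagocytosis genes fell in 21 and rose in 2 of 24 cases (camera adjusted p = 3.67e-05, and adjusted p = 0.329 with an estimated correlation). Fatty acid oxidation genes fell in 16 and rose in 2 of 22 cases, with Cpt1a, which carries fatty acids into mitochondria, at -1.79 (SE 0.06; camera adjusted p = 0.00364, and adjusted p = 0.329 with an estimated correlation). For each list described so far, the counts adjusted over the list alone equalled those over all genes tested. The type I interferon list split, with 11 of 24 genes higher and 10 lower. Ifih1 was at 4.62 (SE 0.06) and Oas2 at -4.32 (SE 0.10), and the list was not called (camera adjusted p = 0.690). Its median lay below 0 while its mean and test pointed up. The 9 lower of the 18 inflammasome genes balanced 9 higher ones, and Nlrp3 rose from 66.6 to 1423 CPM. Glycolysis genes rose in 13 and fell in 5 of 20 cases, and the list was not called (camera adjusted p = 0.0769), except with no filter on low counts (0.0101) and without control replicates 2 and 3 (0.0481). Ribosomal protein genes rose in 15 and fell in 1 of 23 cases (camera adjusted p = 0.0386, and adjusted p = 0.677 with an estimated correlation), a call lost without control replicate 1 (adjusted p = 0.0581) or 3 (0.0670). The counts of these 4 lists were the same when adjusted over the list alone. For the 24 listed ribosomal protein genes, a median of 46.0% of the sequence occurs in transcripts of other genes (highest 94.8%). Changes of the ribosomal protein list are therefore uncertain in each comparison.

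The other lists were not called by camera in LPS against control. Targets of the liver X receptor and lipid efflux genes fell in 13 and rose in 4 of 18 cases, with the desaturase gene Scd2 at -6.24 (SE 0.15; camera adjusted p = 0.0551, and 0.0138 with no filter, 0.0321 with a replicate block and 0.0408 without LPS plus BHB replicate 3). Histone deacetylases fell in 11 and rose in 5 of 17 cases, and cell cycle genes fell in 16 and rose in 5 of 25 (9 and 5 without control replicates 2 and 3). In the tricarboxylic acid cycle list 11 of 21 genes fell and 7 rose. Idh1, the cytosolic isocitrate dehydrogenase, went from 408 to 27.1 CPM, while Dld was at 2.15 and Cs at 1.40. Of 24 nuclear genes of oxidative phosphorylation 12 fell and 6 rose. Cholesterol biosynthesis genes fell in 13 and rose in 5 of 21 cases, while Insig1, a regulator in that list, rose by 3.14 (SE 0.06). Oxidative stress defence genes rose in 7 and fell in 9 of 20 cases (8 and 9 adjusted over the list alone), with Sod2, the mitochondrial superoxide dismutase, going from 49.4 to 1158 CPM. Ketone body genes rose in 5 and fell in 7 of 13 cases, alternative activation markers rose in 4 and fell in 7 of 13, and immediate early genes rose in 5 and fell in 8 of 13. Class I antigen presentation genes rose in 5 and fell in 2 of 9 cases, and class II genes rose in 1 and fell in 2 of 6. These lists had 12 and 11 genes, and several members in the major histocompatibility region of chromosome 17 had few counts, with 7 for H2-D1, 70 for Psmb8 and 1 for H2-Aa over all 9 libraries, so their counts describe only the members that were measured. Of the mitochondrially encoded genes 8 of 11 fell. Among markers of other cell types, neutrophil precursor genes rose in 1 and fell in 5 of 7 cases, dendritic cell genes rose in 4 and fell in 3 of 8, with Cd83 at 3.45 (SE 0.05), and stromal genes rose in 1 and fell in 1 of 12. Except where given, counts adjusted over the list alone were the same.

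In total 11191 of 14026 genes passed the threshold, 5390 higher and 5801 lower with LPS, of which 2626 and 3685 changed at least 2-fold. The groups did not overlap in 82.7% of genes, where chance gives 10%. Scaling by library totals alone gave 4283 higher and 7084 lower and moved the median of all genes by -0.274 (log2), so changes are relative to the TMM scaling, and the ribosomal protein list then lost its call (adjusted p = 0.735). Control replicates 2 and 3 held low counts of LPS-induced genes that control replicate 1 nearly lacked. Acod1 had 24, 1739 and 1808 counts in the 3 control libraries and Il12b had 0, 223 and 213. Tnf, listed at 0 counts in every library, was not tested, nor was Arg1, with 0 to 9 counts per library. Tnf lies in a run of 26 protein-coding genes on chromosome 17, from 35016579 to 35253707 (GRCm38), in which all 9 libraries had 0 counts. Low counts were not confined to this run. Over all 9 libraries Rps28, from 33819027, had 2 counts, Brd2, from 34112023, had 0 and Ddr1, from 35681567, had 9. H2-K1, from 33996017, had 57573. A low count of a gene in this wider region therefore cannot be read as low expression.

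The comparison of LPS plus BHB with LPS asked how adding BHB changed the LPS-treated state. The gene for the anti-inflammatory cytokine interleukin 10, Il10 (chromosome 1, 131019845 to 131024970), rose from 31.2 ± 4.60 CPM with LPS to 238 ± 41.4 CPM with LPS plus BHB (SD, n = 3; log2 fold change 2.94, SE 0.23, adjusted p = 4.54e-05 by edgeR's quasi-likelihood test), against 1.18 CPM in control. Hif1a, which encodes a subunit of the hypoxia-inducible transcription factor (chromosome 12, 73901324 to 73947554), rose from 439 ± 1.71 to 1260 ± 9.21 CPM, and Cd14, an LPS co-receptor gene, from 1651 ± 87.9 to 5765 ± 218 CPM. The largest rises by the fixed rule were those of Ctla2a at 5.75 (SE 0.12), Smad6, an inhibitor of BMP signalling, at 5.25 (SE 0.18), the nuclear receptor gene Nr4a1 at 5.08 (SE 0.41), Plat, tissue plasminogen activator, at 4.85 (SE 0.39), and the growth factor gene Pdgfb at 4.81 (SE 0.15). Pdgfb had 124 CPM in control, 2.89 with LPS and 81.2 with LPS plus BHB. Ctla2a shares 40.2% of its 31-base words with transcripts of other genes, so its value is uncertain. The largest falls were those of the chemokine gene Ccl24 at -4.13 (SE 0.19), the integrin gene Itgb3 at -2.75 (SE 0.14), Slamf8 at -2.67 (SE 0.16), P2ry1 at -2.55 (SE 0.17) and Fam49a at -2.43 (SE 0.07).

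**Figure D2:**
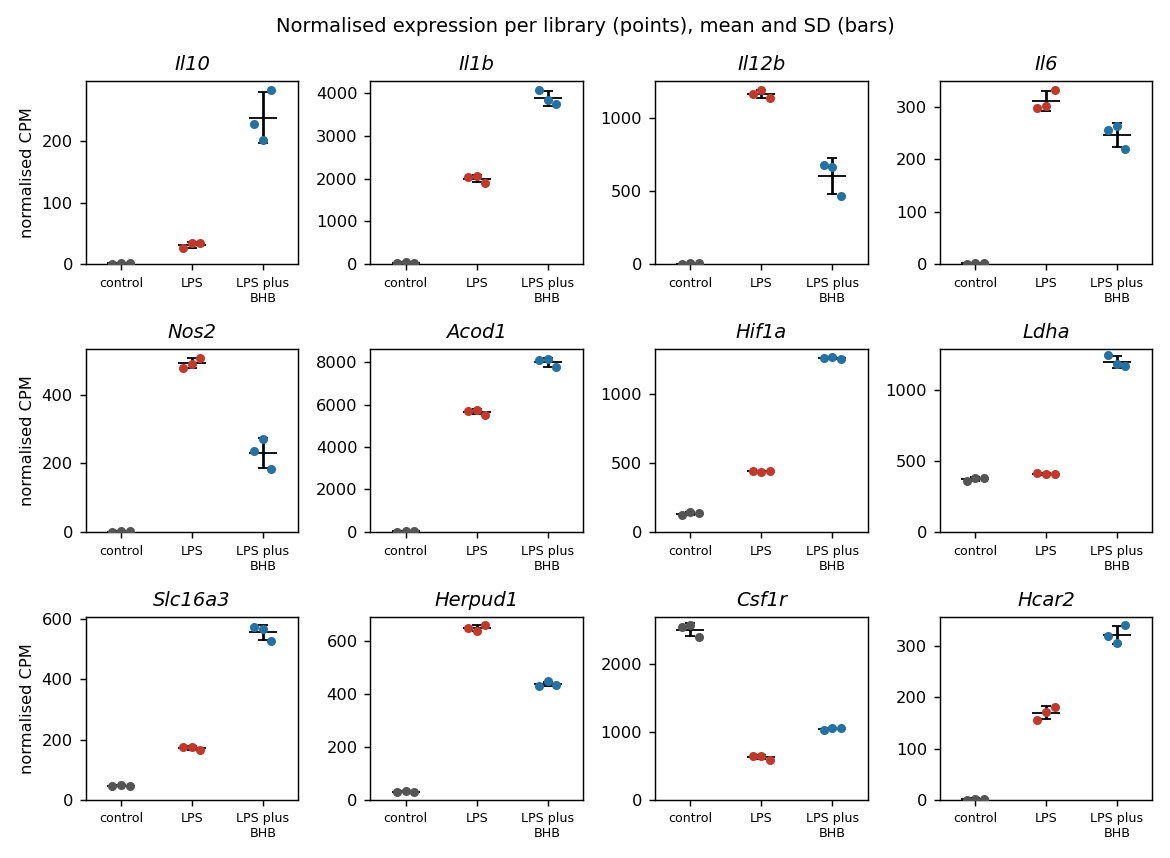
Normalised CPM (y axis, linear, each panel with its own scale from 0) of 12 genes in the 3 groups (x axis), with one point per library and bars for mean and SD over 3 libraries. Il10 went from 31.2 to 238 CPM and Hif1a from 439 to 1260 CPM between LPS and LPS plus BHB, while Il12b and Nos2 were lower with LPS plus BHB.

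Glycolysis genes rose with BHB in 16 and fell in 1 of 20 cases (17 and 1 adjusted over the list alone), with a median log2 fold change of 0.68. Ldha, lactate dehydrogenase A, went from 410 ± 5.55 to 1199 ± 41.3 CPM (log2 fold change 1.55, SE 0.05), and Tpi1 from 186 ± 4.09 to 577 ± 35.7 CPM (1.63, SE 0.05; camera adjusted p = 1.80e-06 for the list, and adjusted p = 0.379 with an estimated correlation). Slc16a3, a lactate exporter gene in the ketone body list, rose from 173 to 557 CPM, while that list had 5 of 13 genes higher and 3 lower and was not called. Inflammasome and pyroptosis genes rose in 13 and fell in 3 of 18 cases (13 and 3 adjusted over the list alone; camera adjusted p = 0.0119, and adjusted p = 0.373 with an estimated correlation). Mefv, which encodes the sensor pyrin, rose by 1.60 (SE 0.06), and the protease genes Casp1 at -1.31 (SE 0.06) and Casp4 at -1.14 (SE 0.05) fell, as did Nlrp3 at -0.29 (SE 0.06). Feedback inhibitors rose in 14 and fell in 3 of 20 cases (14 and 3 adjusted over the list alone), with Irak3 at 1.19 (SE 0.05) and Zfp36, which destabilises cytokine messages, at 1.21 (SE 0.06; camera adjusted p = 0.0229 for the list, and adjusted p = 0.680 with an estimated correlation). Immediate early genes rose in 8 and fell in 2 of 13 cases (8 and 2 adjusted over the list alone), with Fos going from 1.25 to 8.15 CPM, against 152 in control. This call (camera adjusted p = 0.0362, and adjusted p = 0.680 with an estimated correlation) was lost without LPS replicate 3 (adjusted p = 0.0728), with a replicate block (0.0563) and without control replicates 2 and 3 (0.0564).

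The integrated stress and unfolded protein response list fell in 16 of 20 cases with none higher (16 lower and 1 higher adjusted over the list alone), with a median of -0.44. Ern1, a stress sensor of the endoplasmic reticulum, went from 208 ± 8.92 to 84.2 ± 8.83 CPM (log2 fold change -1.31, SE 0.06), Herpud1 from 649 to 438 CPM and Ddit3 from 353 to 241 CPM (camera adjusted p = 0.000239 for the list, and adjusted p = 0.701 with an estimated correlation). Herpud1 and Ddit3 stayed above their control levels of 30.03 and 23.6 CPM. Inflammatory cytokines and chemokines went both ways. Of 23, 3 rose and 6 fell (3 and 5 adjusted over the list alone), including Lif at 2.74 (SE 0.17), Il15 at -1.26 (SE 0.05) and Ccl22 at -1.12 (SE 0.10), and the list was not called (camera adjusted p = 0.731). Its median and test pointed down and its mean up. Il1b rose from 2000 ± 82.6 to 3878 ± 177 CPM (adjusted p = 0.0170), a call lost without LPS replicate 1 (adjusted p = 0.0550), 2 (0.0547) or 3 (0.0611) and without LPS plus BHB replicate 1 (0.0517). Nos2 went from 493 ± 15.4 to 231 ± 43.9 CPM (adjusted p = 0.0110, and 0.481 by DESeq2). The fits in which these calls were lost included the control libraries. Il1b and Nos2 both stayed under the threshold in the fit of the 6 libraries of both groups alone. By library Il1b was at 1904 to 2052 CPM with LPS and 3731 to 4074 CPM with LPS plus BHB. Nos2 was at 479 to 510 and 184 to 271 CPM. Il6 at -0.33 (SE 0.21), Il12b at -0.95 (SE 0.43) and Acod1 at 0.50 (SE 0.87) did not pass in the fit of 9 libraries, whose spread includes the control libraries (adjusted p = 0.239, 0.120 and 0.675). Fitted on the 6 libraries of both groups alone they passed, with adjusted p = 0.000267, 0.00715 and 3.10e-09, and the inflammatory list had 6 genes higher and 12 lower in that fit. The 3 genes also passed without control replicate 1 (0.000185, 0.00150 and 5.18e-09).

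**Figure D3:**
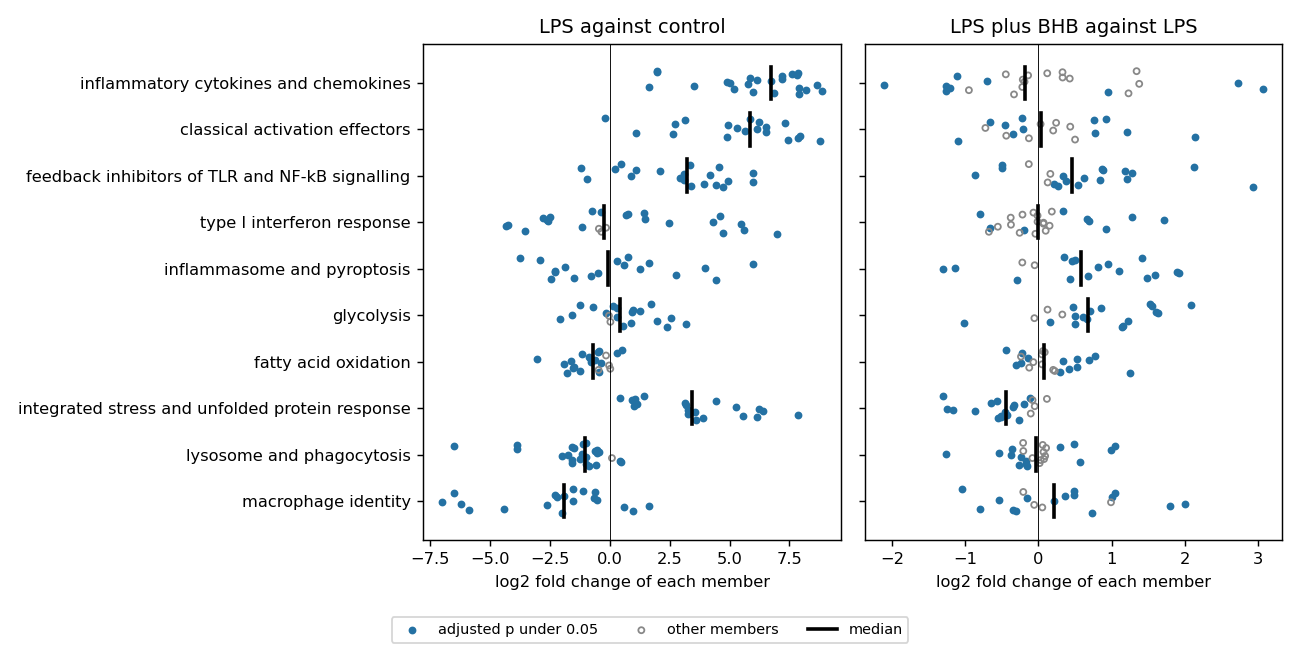
Log2 fold change (x axis) of each tested member of 10 fixed gene lists (y axis) for LPS against control and for LPS plus BHB against LPS, with filled points for members with adjusted p under 0.05, open points for the rest and a black bar for the list median. With BHB the median was 0.68 for glycolysis and -0.44 for the stress response list.

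Other lists held genes that changed without a call for the list. Alternative activation markers had 2 of 13 genes higher and 7 lower, with Mrc1, the mannose receptor gene, going from 175 ± 25.7 to 87.1 ± 9.90 CPM and Myc at -1.19 (SE 0.11). Type I interferon genes had 6 of 24 higher and 3 lower, and 7 and 7 both in the fit of the 6 libraries compared and without control replicates 2 and 3. Components of Toll-like receptor signalling had 12 of 24 higher and 4 lower, with Tlr2 rising from 535 to 1216 CPM. Cpt1a rose from 93.9 to 223 CPM in a fatty acid oxidation list of 22 with 8 higher and 5 lower. Hcar2, a receptor gene for hydroxybutyrate, went from 170 ± 12.8 to 322 ± 17.8 CPM (adjusted p = 0.00757, and 0.233 by DESeq2 over all 9 libraries). Hcar2 stayed under the threshold in the fit of the 6 libraries compared. By library it was at 157 to 182 CPM with LPS and 306 to 341 CPM with LPS plus BHB. Bdh1, the gene of the enzyme that oxidises hydroxybutyrate, was at -0.89 (SE 0.54) and did not pass, except without LPS plus BHB replicate 2 (adjusted p = 0.0208). Cxcl10 was at 0.33 (SE 0.23) and did not pass. Of the histone deacetylases 7 of 17 were higher and 4 lower (8 and 4 adjusted over the list alone), with Hdac7 at 2.04 (SE 0.20). Markers of neutrophil precursors had 3 of 7 genes higher and 1 lower, and those of dendritic cells 1 of 8 higher and 3 lower (2 and 3 of the 6 tested in the fit of the 6 libraries compared), with Cd83 at -1.09 (SE 0.04). Except where given, the counts of these lists adjusted over the list alone were the same.

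Macrophage identity genes rose in 9 and fell in 6 of 19 cases with BHB. Csf1r, the receptor gene for macrophage colony-stimulating factor, went from 629 ± 31.6 to 1049 ± 10.6 CPM, and the transcription factor gene Irf8 from 114 ± 5.78 to 55.4 ± 3.11 CPM. Lysosome and phagocytosis genes rose in 5 and fell in 9 of 24 cases, and classical activation effectors rose in 5 and fell in 6 of 19. Liver X receptor targets and lipid efflux genes rose in 8 and fell in 3 of 18 cases (8 and 4 adjusted over the list alone), with Fabp5, a fatty acid binding protein gene, falling from 203 ± 10.7 to 72.8 ± 0.470 CPM. Cell cycle genes fell in 9 and rose in 2 of 25 cases, with the replication factor gene Mcm4 at -0.98 (SE 0.07). Tricarboxylic acid cycle genes fell in 10 and rose in 4 of 21 cases, nuclear genes of oxidative phosphorylation fell in 7 and rose in 4 of 24 (7 and 2 in the fit of the 6 libraries compared), and cholesterol biosynthesis genes fell in 5 and rose in 4 of 21. Oxidative stress defence genes rose in 10 and fell in 7 of 20 cases, with Gclc, which encodes a subunit of the first enzyme of glutathione synthesis, at -0.96 (SE 0.07). Class I antigen presentation genes rose in 1 and fell in 4 of 9 cases, with Erap1 at -0.98 (SE 0.06), and 1 of 6 class II genes rose. Of the mitochondrially encoded genes 1 rose and 2 fell among 11, of the stromal markers 1 rose and 1 fell among 12, and of the ribosomal protein genes 5 fell among 23 (4 adjusted over the list alone). None of these lists was called by camera, and the other counts adjusted over the list alone were the same.

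In total 7115 of 14026 genes passed the threshold, 3697 higher and 3418 lower with BHB, of which 1106 and 471 changed at least 2-fold. The groups did not overlap in 56.7% of genes, where chance gives 10%. Scaling by library totals alone gave 3297 higher and 3987 lower, so which direction was in the majority depended on the scaling. Tested against a fold of 1.5 the count was 1776. Ldha and Tpi1 are uncertain because 34.2% and 18.5% of their 31-base words occur in transcripts of other genes.

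Of the 11191 genes changed by LPS, 4415 (39.5%) moved back with BHB, that is they changed in the opposite direction, and 1831 (16.4%) moved further in the same direction. Genes that LPS raised at least 2-fold numbered 2626, of which 1119 fell and 541 rose with BHB, with a median log2 fold change of -0.19. Of 3685 genes that LPS lowered at least 2-fold, 1444 rose and 311 fell, with a median of 0.37. Against control the raised genes had a median of 1.77 with LPS and 1.68 with LPS plus BHB, and the lowered genes -1.94 and -1.61. Both comparisons share the LPS libraries, which gives a negative relation with no effect at all. Across genes, which are not independent replicates, Pearson's r was -0.328 and Spearman's rho -0.339, while 20 simulations of unchanged groups gave a mean r of -0.511. The covariance was -0.508 against a simulated -0.0257, a difference of -0.482. In 20 further simulations that kept the LPS change and set LPS plus BHB equal to LPS, the mean r was -0.0800, the mean covariance -0.0479 and the number of genes called in opposite directions at most 2. Independent calls would give 1313 genes raised by LPS and lowered with BHB and 1529 the other way, where 2248 and 2167 were seen. The 3 shared libraries cannot be parted into sets of at least 2. In those further simulations a mean of 0.55 genes passed with BHB. Few opposite calls could therefore arise, and the maximum of 2 cannot be set against the 4415 seen. The simulated covariance of -0.0479, against -0.508 seen, argues against the spread between the shared libraries as the main source of the negative covariance. How much that spread adds to the excess of opposite calls was not tested. A deviation common to all 3 LPS libraries was not simulated and may add to the excess.

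**Figure D4:**
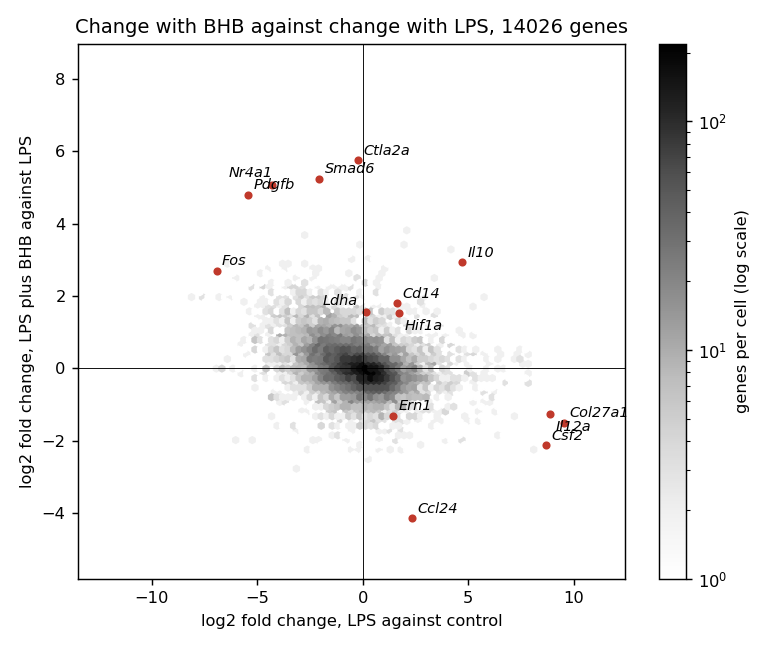
Log2 fold change with BHB (LPS plus BHB against LPS, y axis) against that with LPS (LPS against control, x axis) across 14026 genes, with shading for the number of genes per cell on a log scale and 14 named genes as red points. Pearson's r was -0.328, and both axes share the LPS libraries.

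The comparison of LPS plus BHB with control asked what remained different from untreated cells. Among the largest rises by the fixed rule were those of Cdc42ep1 at 8.70 (SE 0.27), Olr1, a receptor gene for oxidised lipoprotein, at 8.68 (SE 0.30) and Gfi1 at 8.56 (SE 0.37). Has1, a hyaluronan synthase, had 3 control counts, a ratio of 570 with a counting interval of 195 to 2769. Against control replicate 1 alone Cdc42ep1, Gfi1 and Has1 were at least 786-fold, 717-fold and 186-fold higher, and the ratio for Olr1 was 1438 (398 to 11879). Cd300lb fell from 459 ± 16.2 to 3.63 ± 0.436 CPM (log2 fold change -6.98, SE 0.08) and Abcd2 had a log2 fold change of -6.97 (SE 0.14). Nxpe5 and Npas4 had 3 and 2 counts with LPS plus BHB, with ratios of 912 (312 to 4425) and 864 (239 to 7135).

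All 23 inflammatory cytokines and chemokines remained above control, with a median log2 fold change of 6.95, or 6.68 with the gene near the count floor set at its bound. Against control replicate 1 alone 22 passed, with a median of 8.23 with 4 genes at their lower bound. Of 20 glycolysis genes 16 rose and 4 fell, with Hif1a at 3.25 (SE 0.05) and Pfkl at 3.20 (SE 0.05). Stress response genes rose in 19 of 20 cases, feedback inhibitors rose in 19 and fell in 1 of 20, classical effectors rose in 18 and fell in 1 of 19, and Toll-like receptor components rose in 15 and fell in 7 of 24. Macrophage identity genes fell in 16 and rose in 3 of 19 cases, lysosome and phagocytosis genes fell in 20 and rose in 3 of 24, and fatty acid oxidation genes fell in 15 and rose in 2 of 22. Adjusted over the list alone the counts of these 9 lists were the same except 16 higher for Toll-like receptor components. These 9 lists were called by camera, with adjusted p-values from 1.24e-07 to 0.0124, and each had adjusted p = 0.312 with an estimated correlation. Cell cycle genes fell in 18 and rose in 4 of 25 cases (the same adjusted over the list alone), and that list was not called (camera adjusted p = 0.0689), except with no filter on low counts (0.0192), with a replicate block (0.0236) and without control replicate 1 (0.0432) or LPS plus BHB replicate 3 (0.0304). Ribosomal protein genes rose in 13 of 23 cases (12 adjusted over the list alone), and that list was not called (camera adjusted p = 0.0740), except with no filter (0.0192), in the fit of the 6 libraries compared (0.0499) and without control replicate 2 (0.0470), LPS replicate 3 (0.0469) or LPS plus BHB replicate 2 (0.0322). Liver X receptor targets and lipid efflux genes fell in 13 and rose in 4 of 18 cases (camera adjusted p = 0.129, and 0.0493 with no filter), and nuclear genes of oxidative phosphorylation fell in 16 and rose in 7 of 24 (camera adjusted p = 0.200, and 0.0342 with library totals alone). Slc16a3 stood at 3.59 (SE 0.05) and Oxct1, which starts ketone body use, at -2.76 (SE 0.06). In total 10990 genes passed, 5328 higher and 5662 lower, and 3922 and 7366 with library totals alone, which moved the median by -0.326 (log2). Rplp0, higher under TMM scaling, then had a log2 fold change of -0.04. Of its 31-base words 53.3% occur in transcripts of other genes. The change of the ribosomal protein list is uncertain for the same reason.

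Of the 11191 genes changed by LPS, 9460 (84.5%) were changed in the same direction with LPS plus BHB against control and 418 in the opposite one. Across genes r was 0.908 and rho 0.895, with a simulated r of 0.489 for unchanged groups sharing the control libraries. The covariance was 3.17 against a simulated 0.0243, a difference of 3.15. Independent calls would give 2047 genes higher in both and 2342 lower in both, where 4555 and 4905 were seen. The control libraries cannot be parted in that way either, so part of the excess may come from them.

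**Figure D5:**
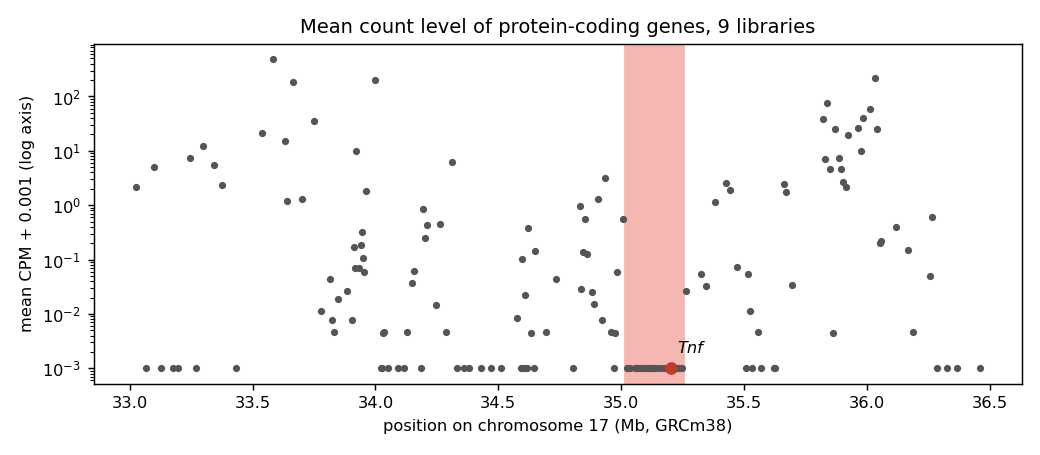
Mean CPM over 9 libraries, scaled by library totals without TMM, plus 0.001 (y axis, log scale) of protein-coding genes by position on chromosome 17 (x axis, Mb, GRCm38), one point per gene. The shaded stretch from 35016579 to 35253707 holds 26 genes with 0 counts in every library, among them Tnf (red). Other genes outside the shaded stretch also had few or no counts.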

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

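Scaling by library totals, the non-robust prior and leaving out control replicates 2 and 3 were tried only after the results were seen. Of the genes selected for naming, 95 of 110 for LPS against control, 72 of 117 for LPS plus BHB against LPS and 97 of 111 for LPS plus BHB against control kept direction and side of the threshold in all 18 settings tried. Of the 28 lists 4, 11 and 3 did so in all 17 settings, which include fry and the estimated correlation. Tested against a fold of 1.5, a stricter null, 7533 genes changed with LPS against control, 3369 higher and 4164 lower. With BHB against LPS 1776 changed, 1205 higher and 571 lower. With LPS plus BHB against control 6992 changed, 3265 higher and 3727 lower. Camera with an estimated correlation called 0, 0 and 0 lists, and fry, which does not compare a list with other genes, called 24, 17 and 25. The share moved back was 36.797% with no filter, 37.404% with DESeq2, 40.781% in fits of 2 groups and 38.313% with library totals; the cause was not tested. Leaving out one library gave 10924 to 11535 changed genes for LPS against control (5257 to 5513 higher, 5665 to 6022 lower, 8 to 10 lists), 6509 to 7071 for LPS plus BHB against LPS (3381 to 3674, 3127 to 3397, 4 to 5 lists), and 10666 to 11188 for LPS plus BHB against control (5196 to 5450, 5458 to 5750, 9 to 10 lists). It gave 35.388% to 39.193% moved back and 9107 to 9586 changed alike. Reversed were Rplp0, LPS plus BHB against control, with library totals (-0.0356), Acta2, LPS against control, without control replicates 2 and 3 (0.2614), and with fry the cholesterol biosynthesis list in LPS against control (adjusted p = 0.003531) and LPS plus BHB against control (0.03928) and the stromal list in the latter (0.01245); the cause was not tested. With the replicate number as a block, the counts were 11136, 7010 and 10908. Libraries with the same number showed no strong common deviation, with correlations from -0.0166 to 0.0392 and 0 of 9 pairs above 0.1. Pairs with different numbers ran from -0.0379 to 0.0430. Among libraries of other groups, 6 of the 9 libraries correlated most with one of their own number, so a weak pairing stays open. A gene with few counts limits the fold that can be read, as for Npas4.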

Other observations

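The class I strain test, both control library tests, the hypoxia and cyclic AMP list tests and the gene-count splits were chosen after the result or part of it was seen. A wider set of hypoxia-inducible factor targets may have risen with BHB. A list of 22 such targets outside glycolysis, written after Hif1a and the glycolysis genes had been seen, had 21 tested genes, of which 18 rose and 2 fell in LPS plus BHB against LPS. Its median log2 fold change was 1.32, at the 100th percentile of 10000 random lists matched on expression, whose central 95% ran from -0.21 to 0.25 (camera p = 9.11e-07, and p = 0.0107 with an estimated correlation). One member, Mxi1, had been seen among the largest rises before the list was written. Without it 17 of 20 rose, with a median of 1.20 and p = 0.0198 with an estimated correlation. Vegfa, chosen with the others named here after its values were seen, went from 60.6 to 289 CPM, Bnip3 from 25.8 to 143 and Egln3 from 1.91 to 15.1, while Ndrg1 fell from 750 to 305 CPM and Cited2 from 250 to 115. This is a hypothesis found and tested on the same libraries, and no protein or oxygen level was analysed here.

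The rises of Nr4a1, Plat and Il10 led to a second list, of 18 cyclic AMP and CREB targets, of which 16 were tested, 8 rose and 3 fell. Its median of 0.20 lay at the 89.24th percentile of random lists and did not decide the question. Without Fosl2, Nr4a3 and Gem, which had been seen earlier, it lay at the 75.85th.

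The rise of glycolysis genes and the fall of stress response genes with BHB were set against technical explanations. After a correction for GC content and transcript length, glycolysis kept 81.2% of its median and the stress response list 117%, which argues against that trend as the whole cause. The 11 glycolysis genes with at most 10% shared 31-base words had a median of 0.66, with 8 higher and 1 lower. This argues against reads shared with pseudogenes as the source of the rise in these 11, which include Hif1a. Members with more shared words, such as Tpi1 (18.5%) and Ldha (34.2%), are not covered. The list percentile of 100 above is in line with a hypoxia-inducible factor response. Effects of BHB through another route stay open, since no library had BHB alone.

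Control replicates 2 and 3 held transcripts that LPS induces. In 27 genes with at least 50 CPM in a treated group and at most 0.1% of that in control replicate 1, the excess in control replicate 2 was fitted by 0.222% of the LPS profile plus 0.349% of the LPS plus BHB profile, and in control replicate 3 by 0.194% plus 0.505%. The excess over the fit spanned at most 1.43-fold between quartiles, consistent with reads of the treated libraries in these control libraries. The lower 95% bound of the LPS plus BHB share was 0.210% or more in both, which argues against activation with the profile of the LPS libraries. Activation with another profile was not tested and stays open.

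A run of 26 protein-coding genes in the major histocompatibility region, with Tnf, Lta, Ltb, Bag6 and Ddx39b, had 0 counts in all 9 libraries (the genes other than Tnf were chosen after their values were seen). Their transcripts shared a median of 0% of 31-base words with other annotated genes, against 46.0% for ribosomal protein genes, which argues against reads lost to annotated copies. Of 6 class I genes nearby, 33.3% had more than 1 CPM in every library, so strain variants cannot be told apart from other causes. The genes below that level, H2-D1, H2-Q4, H2-Q6 and H2-Q7, lie next to the run, and H2-K1 and H2-T23 lie farther away. The low values may therefore be part of the same loss, and the test cannot decide. The class I test was first set on H2-K1 alone, at 171 to 248 CPM, which argued against strain variants. It was widened to 6 genes after that value was seen, because 1 gene cannot decide for a region. Copies of the region on alternate sequences of the authors' index were not tested, and no biological explanation was tested.

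For each comparison the 6 libraries have 10 splits into groups of 3, too few for a share under 0.05. The real splits gave 11191, 7115 and 10990 genes by edgeR, and the highest of the other splits 0, 0 and 0, with 77, 404 and 102 at an unadjusted p under 0.05. In each, 1 of the 10 splits, the real one, gave as many genes. For the lists, the real splits gave 9, 5 and 9 camera calls and the highest of the others 10, 5 and 9. As many calls came from 3, 2 and 5 of the 10 splits. Each split other than the real one mixes libraries of both groups. The group difference then adds to the spread, and part of it stays between the mixed groups. The low gene counts of those splits were therefore fixed by the design. Neither the gene counts nor the list counts there give a level expected without an effect.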
